A study of Mus musculus with 2 samples.

How the data were processed

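The data are 2 Agilent two-colour arrays of 1 design, hybridised with RNA from GFPhigh and GFPlow cells in a dye swap. Per the labels' protocols, RNA was isolated with Trizol and 150 ng of total RNA was labelled with a linear amplification kit. Each file gives 45018 spots of the 45220 positions of the array, and the other 202 were not analysed here. Of these spots 43379 carried gene probes.

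The authors deposited the scanner output. Spot brightness is given as mean intensity per channel with the median intensity of the local background, per the file headers. The files also hold processed intensities, which per the file headers were background-subtracted, detrended and dye-normalized (linear and LOWESS) by Feature Extraction. The deposited log10 ratio is the log10 of processed Cy5 over Cy3. The p-value of each log10 ratio comes from the error model of Feature Extraction for a single array, per the file headers, and covers technical error. The headers name Feature Extraction 10.5.1.1, while the submitters' processing notes name version 9.5.3. A value table of the whole series was set against the scanner values. It holds these log10 ratios turned to GFPhigh over GFPlow, with differences of at most 0.0050 log10 on array 2 and 0.0000 on array 1, and has column medians of 0.0188 for array 1 and -0.0458 for array 2. It is empty at 22558 and 24241 spots, all of which have a scanner ratio of exactly 0. Its scale, direction and centring were thereby settled, and it served as an alternative.

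Mean signals were background-corrected with limma 3.58.1 in R 4.3.3 (normexp, offset 50, local background median) and normalized by loess within each array, with control spots at weight 0. Offset and normexp pull the ratios of dim probes towards 0. Spots marked as non-uniform or as population outliers in either channel were left out, and no gene spot was saturated. Ratios were turned to GFPhigh over GFPlow by the dyes in the labels, and spots of a probe were averaged. A probe was kept where the brighter population was well above background on both arrays. Each gene was represented by its kept probe with the highest average signal. Of 1472 genes with several kept probes, 0 had probes with opposite calls and 55 had probes of which some passed 2-fold and some did not.

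Symbols came from a RefSeq gene table of assembly GRCm38.p6, used for names only. Of 41174 probes, 25097 were named through their accession, 156 through another accession, 6233 by an unchanged symbol and 1610 by an older symbol. The name in the file was kept for 8078. Among the counted genes, 9 of 138 and 10 of 211 had an identifier only.

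A gene was counted as higher in a population when its ratio was at least 2-fold on each array in the same direction. Where 1 population was not well above background on either array, the ratio is a bound. The bright population's mean level was set against the dim population's mean of, per array, the higher of its own level and the lowest level among probes well above background. Levels were taken per channel after loess and Aquantile normalization. List medians use the ratios of such members, and with the bounds in their place only the DNA replication median changed, to -1.25. Besides Smoc2, Mcm10 and Uhrf1, the named genes Tnfrsf19, Myc, Krt10, Ihh, Notch2, Jag1, Fcer1g and Egfl7 were above background on 1 array only in 1 of the populations. For 24 gene lists, the median of the measured members was placed among medians of 10000 random gene lists of the same size, drawn from the same signal deciles. A list with fewer than 3 measured members got no median.

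Design, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Named were Lgr5, the crypt stem cell list with values for up to 8 members, and in each direction the 12 genes with the largest ratios among genes above background in both populations on both arrays. To these were added up to 6 genes per direction measured in 1 population with the highest bounds of at least 2-fold. Of every other list up to 4 members with the largest absolute ratios were named. Identifier-only names were left out of the 12 and the 6. The arrays share 1 slide and 1 scan, so no batch was tested.

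Alternatives covered the background correction, the signals, the centring, the filter, the probe rule, the threshold, the value table and each array alone. Spike-in centring, lists without shared members and lists without their member of largest ratio were added after the data were seen. In spike-in centring, the mean turned ratio of 10 spike-in probes was set to 0.

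The steps were tested on simulated arrays with the real signal levels, a dye curve and 200 genes changed by known folds, over 9093 genes. The changed genes were drawn only from genes with a mean net signal above 200. The shares counted below therefore do not cover dim genes. For the simulated GFPhigh over GFPlow ratio, 66.0% of genes set 3-fold higher in GFPhigh and 70.0% of those set 3-fold higher in GFPlow were counted. Of those set 6-fold apart, 100% and 98.0% were counted. None of 8896 unchanged genes was counted, and no direction was wrong. The simulated SD per array was 0.268, lower than the 0.394 of the real ratios. With the noise raised to an SD per array of 0.386, 1 of 8906 unchanged genes was counted, with 67 of 100 genes set 3-fold apart and 99 of 100 set 6-fold apart. Both simulated populations had the same signal levels, and all genes the same relative noise. The real arrays had fewer probes above background in GFPhigh (7448) than in GFPlow (9966). The share of unchanged genes counted therefore does not carry over to the real data. The median ratio of genes set 6-fold higher in GFPhigh was 2.25 in place of 2.58. The simulated dye curve compresses ratios too, so this value cannot be credited to offset and normexp alone. Of 400 random lists, 4.00% fell outside the 2.5th to 97.5th percentile. These lists were drawn from unchanged genes with independent noise, so a small share follows from the setting. It says nothing about lists whose genes move together.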

Results

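Gene expression was measured in epithelial cells from the pylorus, the part of the stomach that leads into the intestine, of Lgr5-EGFP-ires-CreERT2 knock-in mice. In this strain green fluorescent protein (GFP) is expressed from the Lgr5 locus, so that its brightness follows Lgr5, a Wnt pathway receptor used as a stem cell marker in several epithelia. The pyloric tissue of 20 stomachs from 20 mice was dissociated and sorted by flow cytometry into a population with high GFP (GFPhigh) and a population with low GFP (GFPlow). RNA of both populations was labelled with Cy3 and Cy5 and hybridised together on 2 Agilent mouse arrays, with the dyes exchanged between the arrays. GFPhigh was in Cy3 on array 1 and in Cy5 on array 2. The labels describe 1 RNA sample per population, so the 2 arrays are repeat measurements of 1 replicate. No test between the populations was possible, and no p-value is given. Every value below is a log2 ratio of GFPhigh over GFPlow, as the mean ± SD of the 2 arrays, and the SD holds technical error only. A positive value is higher in GFPhigh. The number of arrays limits the precision.

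On array 1, 28.6% of gene spots were well above background in the GFPhigh channel and 25.1% in the GFPlow channel. On array 2 the shares were 18.7% for GFPhigh and 31.7% for GFPlow. Of 41059 probes left after flagged spots were removed, 7448 were above background on both arrays in GFPhigh and 9966 in GFPlow. The comparison covered 9499 probes of 7830 genes, those with the brighter population above background on both arrays. Across these probes, which are not independent replicates, the 2 arrays correlated with a Pearson coefficient of 0.595 and a Spearman coefficient of 0.474. The SD of the difference between the arrays was 0.56. Only 4 genes were at least 2-fold apart in opposite directions on the 2 arrays.

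Lgr5 itself was higher in GFPhigh, as the labels of the sort require. Its log2 ratio was 2.33 on array 1 and 2.24 on array 2, a mean of 2.28 ± 0.06, or 4.86-fold. It ran from 1.497 with spike-in centring to 3.17 with the processed signals of the scanner software, so the size of this difference depends on the processing. This probe lies on chromosome 10 between positions 114888847 and 114888906 of the mm9 build that the file headers name. A further probe given to Lgr5, at positions 114900686 to 114900745, was not well above background in any channel and gave no level. No gene annotation of this build was used here, so the exon of each probe is not given.

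The question of the design was which genes differ between cells with high and low Lgr5 expression. At least 2-fold differences in one direction on both arrays were found for 138 genes higher in GFPhigh and 211 genes higher in GFPlow. The genes with the largest ratios towards GFPhigh included Cblif, Pgc and Gkn3, which encode secreted stomach proteins, and those towards GFPlow included Chia1, Gkn2, Tff1, Gsta1 and Ghrl. With centring on the array median in place of loess, the split was 10 against 215 genes, and the median of all genes moved from -0.06 to -0.49. With centring on spike-in RNA, an alternative added after the data were seen, it was 21 against 1643 genes with a median of -0.84. The 138 to 211 split is therefore relative to the average gene. With the processed signals of the scanner software the counts were 352 and 511. Spike-in centring lowers every log2 ratio below by 0.78.

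**Figure D1:**
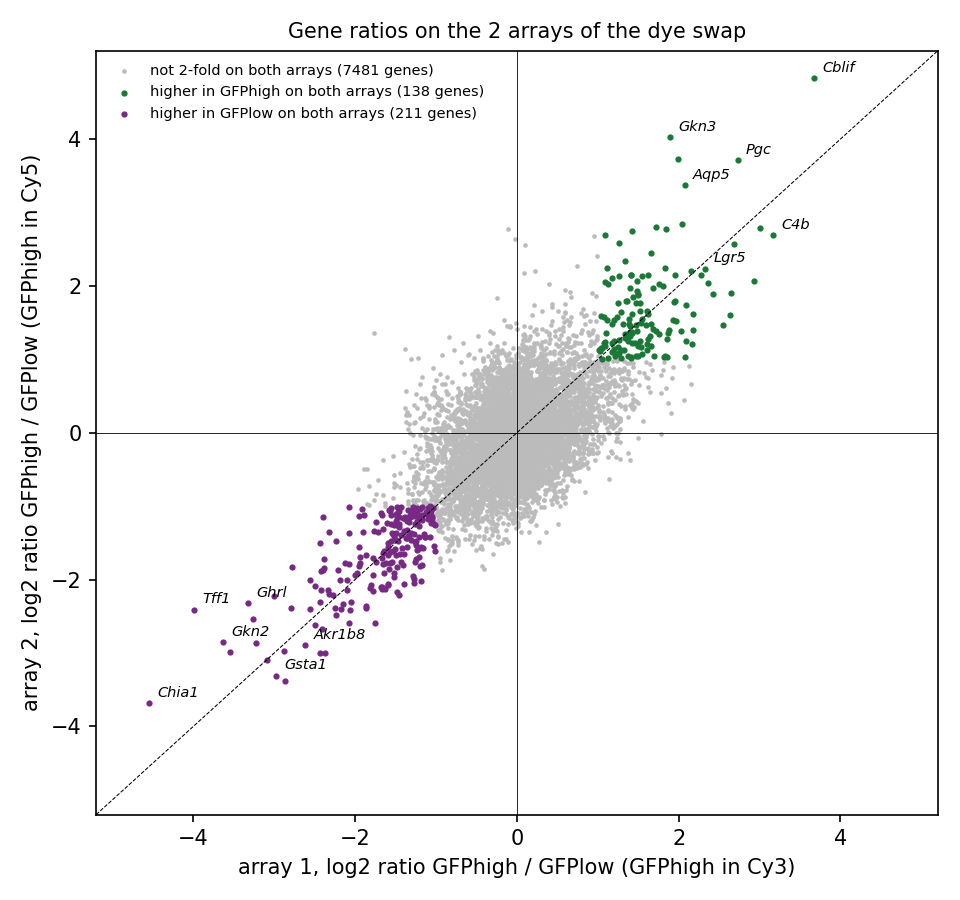
Log2 ratio of GFPhigh over GFPlow of 7830 genes on array 1 (horizontal, GFPhigh in Cy3) and array 2 (vertical, GFPhigh in Cy5), 1 point per gene, with the dashed line marking equal values. The 138 green genes were at least 2-fold higher in GFPhigh on both arrays and the 211 purple genes at least 2-fold higher in GFPlow, while Lgr5 lay near the line at 2.33 and 2.24.

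Among genes measured in both populations, the largest ratio towards GFPhigh was that of Cblif, which encodes gastric intrinsic factor, at 4.25 ± 0.82, or 19.1-fold. Pgc, which encodes the protease precursor progastricsin, followed at 3.22 ± 0.69. Gkn3, a gastrokine, was at 2.96 ± 1.51, with 1.89 on array 1 and 4.02 on array 2. The complement component C4b was at 2.93 ± 0.34, the cilium gene Rsph9 at 2.89 ± 0.16 and the water channel Aqp5 at 2.72 ± 0.92. The elastase gene Cela1 was at 2.63 ± 0.08, the stress-induced regulator Nupr1 at 2.44 ± 0.57 and the pepsinogen gene Pga5 at 2.31 ± 0.66. Lgr5 ranked next, followed by Sec14l4 at 2.27 ± 0.53 and the collagen gene Col11a2 at 2.26 ± 0.77. The C4b probe is uncertain, since the near-identical gene C4a may share its transcripts. Only 2 genes measured in GFPhigh alone had a bound of at least 2-fold. They were Sirpa, a signal-regulatory receptor, at least 2.38-fold higher, and Cckar, a cholecystokinin receptor, at least 2.09-fold higher. Cckar was under 2-fold on array 2 and is not among the 138 genes.

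The largest ratio towards GFPlow was that of Chia1, an acidic chitinase of the stomach, at -4.11 ± 0.61, or 17.3-fold higher in GFPlow. The mucosal glycoprotein gene Dmbt1 was at -3.27 ± 0.39, and the surface mucous cell products Gkn2 and Tff1 were at -3.24 ± 0.55 and -3.20 ± 1.12. The glutathione S-transferase genes Gsta1 and Gsta3 were at -3.14 ± 0.23 and -3.09 ± 0.00. The ratio was -3.12 ± 0.36 for the calcium-binding protein gene S100a6, -3.04 ± 0.26 for Plac8 and -2.92 ± 0.07 for C2cd4a. Chgb, a protein of hormone granules, was at -2.90 ± 0.51, the stomach hormone ghrelin (Ghrl) at -2.82 ± 0.71 and the aldo-keto reductase gene Akr1b8 at -2.75 ± 0.19. The Gsta1 probe is uncertain because Gsta2 is a close copy. A bound of at least 2-fold was reached by 29 genes measured in GFPlow alone. The highest bounds were those of Slc23a3 (at least 3.35-fold), Oit1 (3.30-fold), the gastrokine Gkn1 (3.07-fold), Tcf23 (2.86-fold), Lgals6 (2.68-fold) and the mitotic kinesin gene Kif4 (2.60-fold). Lgals6 has close copies and is uncertain.

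Stem cell genes known from the intestinal crypt were higher in GFPhigh as a group. Of 17 measured members, 8 were at least 2-fold higher in GFPhigh on both arrays and 0 were higher in GFPlow. Besides Lgr5 these were the matrix protein gene Smoc2 (2.49 ± 0.61, above background in GFPlow on 1 array), the hyaluronan receptor gene Cd44 (1.70 ± 0.62), the potassium channel gene Kcnq1 (1.61 ± 0.35), Lrig1 (1.42 ± 0.34), the transcription factor gene Sox9 (1.36 ± 0.06), the ubiquitin ligase gene Rnf43 (1.32 ± 0.36) and Tnfrsf19. The members that did not reach 2-fold on both arrays included Ascl2, Ephb2, Ephb3, Prom1, Slc12a2, Msi1, Cdk6, Phlda1 and Cdca7. Olfm4, Axin2 and Znrf3 were among the members not measured. Lgr5 counts among the 17 and the 8, although the sort fixed its direction, and no value without it was computed. The list median was 1.16, at the 100th percentile of 10000 random gene lists of the same size and signal. The percentile describes these RNA samples only, and 13 of 21 lists lay outside the middle 95% of their random lists. The median was 0.65 under median centring, 0.37 under spike-in centring and 0.27 with no filter on dim probes, which raised the list to 26 genes. Without members that other lists also hold it was 0.48, and it stayed above 0 in all alternatives.

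Of 28 Wnt pathway genes on the array only 7 were measured, of which 4 were higher in GFPhigh and 1 in GFPlow. Axin2, Lef1 and Notum were among those not measured. Nkd1 and Sp5, which are induced by Wnt signalling, were at 2.20 ± 0.23 and 1.78 ± 0.41, and Rnf43 and Tnfrsf19 are shared with the crypt list. Myc was lower in GFPhigh, at -1.40 ± 0.23. The median was 1.16 at the 100th percentile, and 0.22 under median centring and 0.37 under spike-in centring. Both this median and that of the crypt list are the ratio of Tnfrsf19 (1.16 ± 0.19), so their equal values are not separate results. Tnfrsf19 was above background in GFPlow on 1 array only. Without members shared with other lists the Wnt median was 0.88 over 4 genes, at the 99.8th percentile. With no filter on dim probes it was 0.0498 over 28 genes, at the 91.3th percentile. The median of the 7 measured genes was 1.07 on array 1 and 1.02 on array 2. With the signal filter set on a single array, the list had other members and its median was 0.27 over 10 genes on array 1 (94.3th percentile) and 0.01 over 9 genes on array 2 (81.0th). Of 10 measured candidate genes for gastric stem and progenitor cells, 2 were higher in GFPhigh (Aqp5 and Lrig1) and 1 in GFPlow, the tubulin regulator Stmn1 at -1.93 ± 0.21. Tff2, a trefoil peptide of gland mucous cells, was at 1.82 ± 1.22 and did not pass on both arrays. The median was 0.93 at the 100th percentile, and 0.48 under median centring and 0.15 under spike-in centring. Without members shared with other lists it was 0.12 at the 77.9th.

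Genes of mucous cells of the neck and gland base were higher in GFPhigh in 5 of 10 measured members and in GFPlow in 0. Pgc, Gkn3, Aqp5 and Creb3l4 (1.84 ± 0.41), a transcription factor of the secretory pathway, were among the 5. The median was 1.75 at the 100th percentile, and 0.85 under median centring and 0.97 under spike-in centring. Of 7 measured chief cell genes, 4 were higher in GFPhigh, with Cblif, Pgc and Pga5 the largest, and Chia1 was higher in GFPlow. Their median was 1.62 at the 100th percentile, and 0.93 and 0.84 under these centrings and 0.94 over 10 genes with no filter. Of 7 parietal cell genes, Kcnq1 was higher in GFPhigh, while Vegfb (0.91 ± 0.56), the carbonic anhydrase gene Car2 (-0.91 ± 0.16) and the proton pump subunit gene Atp4b (0.76 ± 0.56) did not pass. The parietal median of 0.60, at the 99.2th percentile, was 0.0085 under median centring and -0.18 under spike-in centring, and it was at the 97.3th percentile without Kcnq1 and at the 95.5th over 9 genes on array 1 alone.

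Cell cycle genes were higher in GFPlow. Of 28 measured mitotic genes, 19 were at least 2-fold higher in GFPlow on both arrays and 0 were higher in GFPhigh, with a median of -1.30 below all 10000 random lists. The proliferation marker Mki67 was at -2.28 ± 0.20, the survivin gene Birc5 at -2.26 ± 0.10, the kinetochore motor gene Cenpe at -2.13 ± 0.37 and Cdca8 at -2.05 ± 0.47. Of 29 measured DNA replication genes, 16 were higher in GFPlow and 0 in GFPhigh, with a median of -1.26 that was also below all random lists. The ratios were -2.28 ± 0.15 for Mcm10, -1.94 ± 0.04 for Uhrf1, -1.82 ± 0.18 for the licensing factor gene Cdt1 and -1.74 ± 0.04 for the helicase subunit gene Mcm4. GFPhigh was above background on 1 array for Mcm10 and Uhrf1. Among the measured members, 8 mitotic genes and 2 replication genes were above background in GFPlow alone. On both arrays, 15 mitotic and 18 replication genes were above background in GFPhigh, against 28 and 29 in GFPlow. Members not above background in GFPhigh on both arrays could be kept only with a negative ratio. With no filter, which lifts this limit, the medians were -1.28 and -1.24 over 31 genes each, still below all random lists. Over all alternatives the medians ran from -2.14 to -1.11 for mitotic and from -2.05 to -1.15 for replication genes.

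Surface mucous (pit) cell genes were higher in GFPlow in 5 of 11 measured members and in GFPhigh in 0. Besides Gkn2, Tff1 and Gkn1, these included the mucin gene Muc5ac at -2.33 ± 0.37. The median was -0.82 at the 0.01th percentile, and ran from -1.61 with spike-in centring to -0.29 over 15 genes with no filter. Of 17 measured enteroendocrine genes, 5 were higher in GFPlow and 0 in GFPhigh, with a median of -0.87 below all random lists. Only 8 were above background in GFPhigh on both arrays, against 17 in GFPlow, and the others could be kept only with a negative ratio. The median ran from -1.66 with spike-in centring to -0.29 over 32 genes with no filter, which lifts this limit. With no filter it was still below all random lists. Besides Chgb and Ghrl, somatostatin (Sst) was at -1.68 ± 0.03 and chromogranin A (Chga) at -1.46 ± 0.15.

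**Figure D2:**
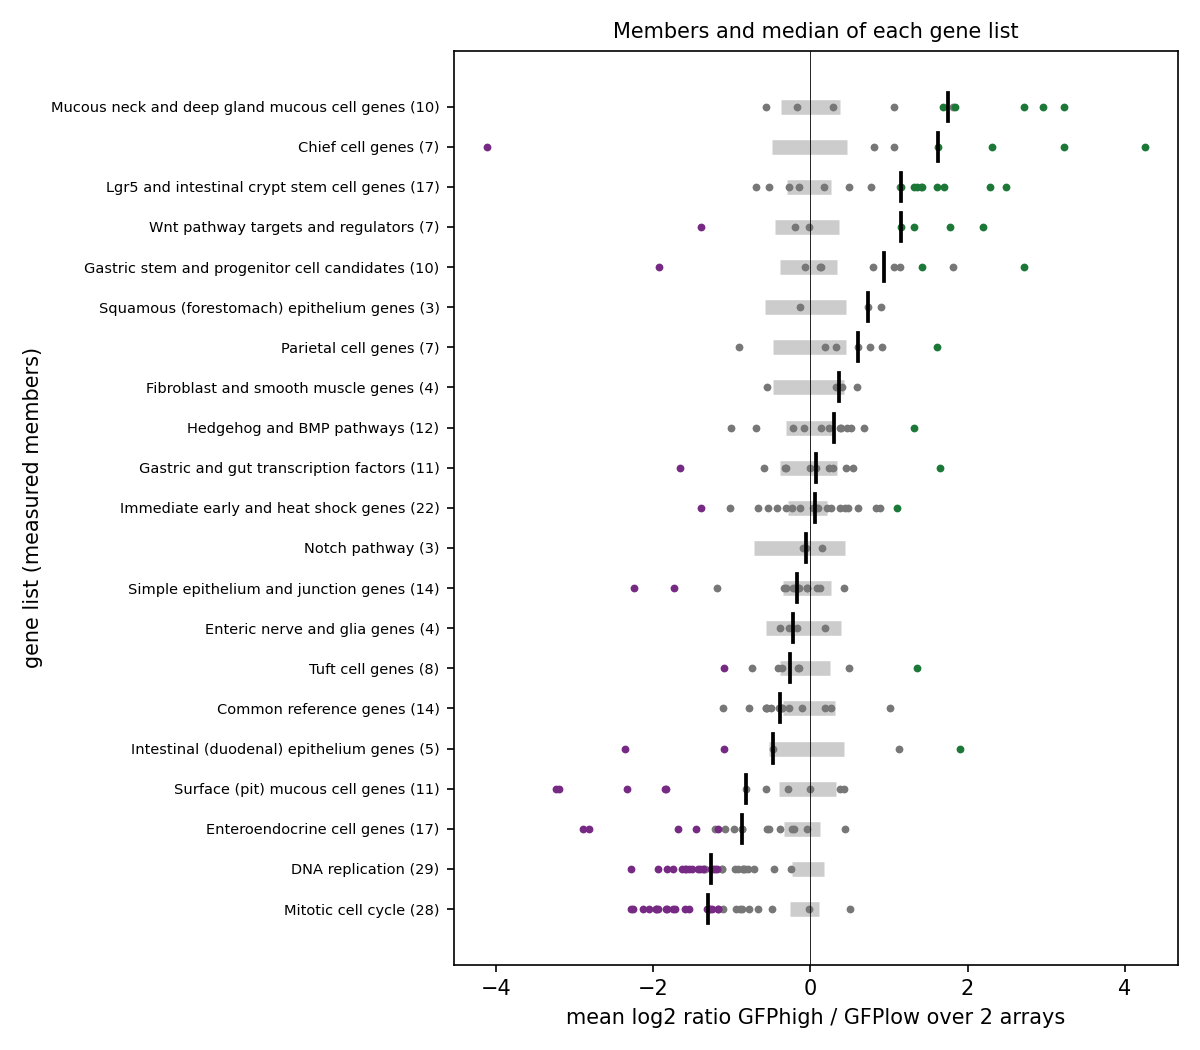
Mean log2 ratio of GFPhigh over GFPlow (horizontal) of the measured members of 21 gene lists, 1 point per gene, green where at least 2-fold higher in GFPhigh on both arrays and purple where higher in GFPlow. Black bars are list medians and grey bands the middle 95% of medians of 10000 random lists, and the medians run from -1.30 for mitotic genes to 1.75 for gland mucous cell genes.

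Of the other epithelial groups, tuft cell and intestinal genes had members at least 2-fold higher in each population. Among 8 tuft cell genes, Sox9 was higher in GFPhigh and Avil, measured in GFPlow alone, at least 2.13-fold higher in GFPlow. Alox5, also measured in GFPlow alone, was at least 1.66-fold higher there and Ascl2 was at 0.50 ± 0.53, and both did not pass. The tuft median of -0.26 was at the 11.5th percentile and was 0.50 over the 3 genes above background in both populations and -1.04 under spike-in centring. Only 2 of the 8 were above 0, Sox9 and Ascl2, both also in the crypt list. Without members shared with other lists the tuft median was -0.38 over 6 genes, at the 4.79th percentile. With no filter it was -0.15 over 20 genes, at the 0.03th percentile. The tuft percentile was 1.97 over 9 genes on array 1 alone and 24.7 over 11 genes on array 2 alone. Among 5 intestinal epithelium genes the peptidase gene Anpep (1.90 ± 0.14) was higher in GFPhigh, and the fatty acid binding protein gene Fabp2 (-2.36 ± 0.18) in GFPlow, as was Clca1, which was measured in GFPlow alone (at least 2.13-fold). Agr2 was at 1.13 ± 1.47, and the intestinal median of -0.48, at the 3.98th percentile, was 1.13 over the 3 genes above background in both populations and -1.26 under spike-in centring. Of 14 genes of simple epithelia and their junctions, the keratin genes Krt19 (-2.24 ± 0.04) and Krt7 (-1.73 ± 0.47) were higher in GFPlow, while Krt8 (-1.19 ± 0.98) and Prss8 (0.43 ± 0.31) did not pass. The simple epithelium median was -0.18 at the 20.4th percentile, and -0.25 on array 1, -0.30 on array 2, -0.81 under median centring and -0.96 under spike-in centring. Squamous epithelium genes had 3 measured members, with Lor at 0.90 ± 0.10, Sbsn at 0.73 ± 0.13 and Krt10 at -0.13 ± 0.33, none past 2-fold on both arrays. Their median of 0.73, at the 99.8th percentile, was 0.35 under median centring, -0.053 under spike-in centring and 0.0038 over 19 genes with no filter, at the 42.8th percentile.

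Among 11 transcription factor genes of the gut, Spdef, a factor of secretory cells, was higher in GFPhigh (1.64 ± 0.18) and Klf4 in GFPlow (-1.66 ± 0.55), with a median of 0.07 at the 69.9th percentile that was 0.34 on array 1, -0.10 on array 2, -0.56 under median centring and -0.71 under spike-in centring. Klf5 (-0.59 ± 0.24) and Foxa3 (0.55 ± 0.47) did not pass. Of 12 Hedgehog and BMP pathway genes, Bmp7 (1.32 ± 0.21) was higher in GFPhigh, and Id1 (-1.01 ± 0.90), Ihh (-0.69 ± 0.13) and Id4 (0.69 ± 0.35) did not pass. The median of 0.31, at the 98.8th percentile, was -0.16 under median centring and -0.48 under spike-in centring. It lay inside the middle 95% of random lists without background correction (94.3th percentile), with the processed signals (96.6th), with no filter (94.0th), without its member of largest ratio (94.3th) and on each array alone (92.9th and 86.0th). The 3 measured Notch pathway genes, Hes6 (0.15 ± 0.44), Notch2 (-0.10 ± 0.10) and Jag1 (-0.06 ± 0.10), had a median of -0.06 at the 71.5th percentile, and of -0.29 under median centring and -0.84 under spike-in centring.

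Genes of cells outside the epithelium were mostly not well above background. Measured were 2 of 34 leukocyte genes, Lcp1 (-0.10 ± 0.30) and Fcer1g (-0.12 ± 0.35), and 2 of 16 endothelial genes, Esam (0.48 ± 0.05) and Egfl7 (-0.62 ± 0.39). Of 11 erythroid genes on the array, Tfrc and Hbb-bt were measured in GFPlow alone, at least 1.31-fold and 1.23-fold higher there. Of 23 fibroblast and smooth muscle genes 4 were measured, with a median of 0.37 at the 95.7th percentile. For these 4 genes it was -0.06 on array 1 and 0.79 on array 2, and it was 0.0336 under median centring and -0.42 under spike-in centring. Of these Col1a2 was at 0.60 ± 0.75, Acta2 at -0.55 ± 0.16, Tagln at 0.41 ± 0.72 and Bgn at 0.33 ± 0.48. Of 14 nerve and glia genes 4 were measured, with a median of -0.22 at the 26.7th percentile, and of -0.57 under median centring and -1.01 under spike-in centring. For these 4 genes it was -0.39 on array 1 and -0.02 on array 2. Uchl1 was measured in GFPlow alone, at least 1.30-fold higher there, with Erbb3 at -0.28 ± 0.29, S100b at 0.19 ± 0.21 and Tubb3 at -0.17 ± 0.28. No member of these 5 lists was 2-fold apart on both arrays.

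Of 22 immediate early and heat shock genes, which respond to tissue handling, 1 was higher in GFPhigh (Dusp6, 1.098 ± 0.081) and 1 in GFPlow (Myc). Hsph1 was at -1.03 ± 0.27 and Klf2 at 0.89 ± 0.09, and the median was 0.06 at the 80.1th percentile and -0.36 under median centring and -0.72 under spike-in centring. None of 14 common reference genes was 2-fold apart on both arrays. Their median was -0.38 at the 1.65th percentile, and -1.10 under median centring and -1.16 under spike-in centring. The percentile was 4.96 on array 2 alone and 2.66 without Tubb5. Of the members, Tubb5 was at -1.104 ± 0.238, B2m at 1.02 ± 0.38, Gapdh at -0.78 ± 0.42 and Hprt at -0.57 ± 0.14.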

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

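The tests in this part were chosen after the result was seen. The 10 spike-in probes, which the comparison of genes left out, read higher in GFPhigh than the sample RNA did. Averaged over both dye orientations, which cancels the dye and the mixes of the spike-ins, their log2 ratio was 0.78 ± 0.19 (SD over 10 spike-in probes), with a range of 0.39 to 1.08. From the processed signals it was 0.88 ± 0.14. In parallel, within each dye GFPhigh had fewer spots well above background than GFPlow had on the other array. Within array 1, GFPhigh had more (28.6% against 25.1%).

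A dye effect is argued against by the average over both dye orientations, which cancels it. The ratio of spots above background, GFPhigh over GFPlow within a dye and across the arrays, was also below 1 in Cy3 (0.903) and in Cy5 (0.743). The tables also argue against the brightness of an array or scan. The spike-in signals of the arrays differed by 0.04 ± 0.03 in Cy3 and 0.11 ± 0.07 in Cy5 on the log2 scale, far below the shift. Less sample RNA in the GFPhigh labelling reactions stays open, with the shift of 0.78 as its value. It cannot be told apart from a lower share of messenger RNA in the total RNA of GFPhigh cells, because each population was 1 RNA sample. The labels give the same 150 ng of total RNA for the labelling with no difference between the populations, and the amount that went into each reaction was not measured here. A biological difference in RNA content between the populations was not tested.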

How the results depend on the processing

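Spike-in centring and changes to list members were chosen after the data were seen. With 1 replicate, the arrays show technical error only, and signal over background limits the comparison to 9499 of 41059 probes. The 64 named genes that were 2-fold apart on both arrays kept their sign in every alternative with a value. For spike-in centring and for 1 array alone this was largely fixed in advance, since each array was past 2-fold. The filter and saturation alternatives reuse the same ratios. The outcome was open only for the background correction, the signals, the value table, median centring and the probe rule. Leaving out 1 array moves a gene by less than the SD of 2 arrays by construction and says nothing about stability. Named genes short of 2-fold changed sign under median centring (Agr2, Ephb2, Hes6, Prss8, S100b), spike-in centring (Ascl2, Atp4b, Bgn, Col1a2, Ephb2, Ephb3, Esam, Foxa3, Hes6, Id4, Prss8, S100b, Sbsn, Tagln) and with the processed signals or the authors' table (Lcp1). They also did so with array 1 alone (Bgn, Krt10, Lcp1, Tagln) and array 2 alone (Ephb2, Hes6, Msi1, Tubb3). Leaving out saturated probes moved nothing, since none was saturated. With no filter on dim probes the counts were 138 and 211, as no probe that the filter removes was 2-fold apart on both arrays. Matching random lists on signal put no list on another side of the middle 95% of random lists. The causes of the changes below were not tested, except that other thresholds and filters change which genes are counted or measured.

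The counts of genes higher in GFPhigh and GFPlow were 352 and 511 with the processed signals, 352 and 507 with the authors' table, 249 and 317 for the mean of the arrays, 438 and 587 at 1.5-fold, 32 and 72 at 3-fold, and 711 and 885 by the scanner software's error model. They were 10 and 215 with median centring and 21 and 1643 with spike-in centring. They were 125 and 139 with both populations above background, 47.3% in GFPhigh against 39.5%, by a filter that removes more genes low in GFPhigh. With 1 array alone, the counts were 348 to 370 for GFPhigh and 397 to 496 for GFPlow. Of the 138 and 211 genes, 134 and 201 were also counted with the processed signals, and 10 and 160 with median centring. The Lgr5 ratio was 1.88 without background correction, 2.61 with offset 10, 3.17 with the processed signals and with the authors' table, 1.798 with median centring and 1.497 with spike-in centring. The correlation of the arrays was 0.528 without background correction, 0.744 with the processed signals and 0.430 with median centring.

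The list medians that moved by more than the SD of the arrays follow. Without background correction they were 1.05 for crypt stem cell, 0.78 for Wnt, -1.11 for mitotic, 1.49 for chief cell, 0.49 for parietal, -0.27 for intestinal, 0.54 for squamous, 0.17 for Hedgehog and BMP and 0.0487 for immediate early genes. With offset 10 they were 1.41 for crypt stem cell and for Wnt, -1.74 for mitotic, -1.42 for replication, -0.68 for pit cell, 1.70 for chief cell, -1.05 for enteroendocrine, -0.36 for tuft, -0.73 for intestinal, 0.89 for squamous and 0.36 for Hedgehog and BMP genes. The processed signals and the authors' table gave 1.41 for crypt stem cell and for Wnt, 1.34 for gastric stem cell, -2.14 for mitotic, -1.68 for replication, -0.98 for pit cell and 1.75 for chief cell genes. They gave -1.64 for enteroendocrine, -0.36 for tuft, -0.77 for intestinal, 1.13 for squamous, -0.26 for simple epithelium, 0.34 for Hedgehog and BMP, 0.14 for immediate early and -0.47 for reference genes.

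Median centring gave 0.65 for crypt stem cell, 0.22 for Wnt, 0.48 for gastric stem cell, -1.90 for mitotic, -1.96 for replication, -1.60 for pit cell, 0.85 for gland mucous, 0.93 for chief cell, 0.0085 for parietal and -1.35 for enteroendocrine genes. It gave -0.71 for tuft, 0.35 for squamous, -0.81 for simple epithelium, -0.56 for transcription factor, -0.29 for Notch, -0.57 for glia, -0.36 for immediate early and -1.10 for reference genes, and it turned the Hedgehog and BMP median to -0.16. The transcription factor and immediate early medians also turned. Spike-in centring turned the medians of parietal (-0.18), squamous (-0.0530), Hedgehog and BMP (-0.48), transcription factor (-0.71), fibroblast (-0.42) and immediate early genes (-0.72). It gave 0.37 for crypt stem cell and for Wnt, 0.15 for gastric stem cell, -2.08 for mitotic, -2.05 for replication, -1.61 for pit cell, 0.97 for gland mucous, 0.84 for chief cell, -1.66 for enteroendocrine and -1.04 for tuft genes. It gave -1.26 for intestinal, -0.96 for simple epithelium, -0.84 for Notch, -1.01 for glia and -1.16 for reference genes.

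The filter on both populations keeps fewer genes that are low in 1 population, so it also picks members by their change. With both populations above background the medians were 1.55 for Wnt, -1.83 for mitotic, -1.33 for enteroendocrine, 0.50 for tuft, 1.13 for intestinal, 0.38 for Hedgehog and BMP and 0.0823 for immediate early genes. With no filter they were 0.27 for crypt stem cell, 0.0498 for Wnt, 0.13 for gastric stem cell, -0.29 for pit cell, 0.94 for chief cell, 0.18 for parietal, -0.29 for enteroendocrine, -0.15 for tuft, 0.0155 for intestinal, 0.0038 for squamous, 0.0679 for Hedgehog and BMP and 0.0406 for immediate early genes. Without shared members they were 0.48 for crypt stem cell, 0.88 for Wnt, 0.12 for gastric stem cell, -1.33 for pit cell, 0.47 for parietal and -0.38 for tuft genes. Without the member of largest ratio they were 0.57 for Wnt, -0.69 for pit cell, 1.35 for chief cell, 0.47 for parietal, -0.36 for tuft, 0.33 for intestinal and 0.23 for Hedgehog and BMP genes.

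With 1 array alone the filter was set on that array, so the members changed too (Wnt from 7 to 10 and 9, intestinal from 5 to 8 and 6, Notch from 3 to 5), and these values are not a spread between arrays. With unchanged members the Wnt medians were 1.07 and 1.02 and the intestinal ones -0.39 and -0.56. With the changed members, medians ran from 0.96 to 1.06 for crypt stem cell, 0.0139 to 0.27 for Wnt, 0.33 to 0.95 for gastric stem cell, -1.42 to -1.38 for mitotic, -1.30 to -1.15 for replication, -0.85 to -0.54 for pit cell, 0.36 to 0.46 for parietal and -0.88 to -0.65 for enteroendocrine genes. They ran from -0.44 to 0.11 for intestinal, -0.36 to -0.24 for simple epithelium, -0.27 to 0.24 for transcription factor and 0.18 to 0.21 for Hedgehog and BMP genes. They were 0.0404 and 0.0410 for immediate early genes, and 0.14 for Notch genes, with too few members on array 2. The 3 Notch genes measured over both arrays had a median of -0.13 on array 1.

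Percentiles that crossed an edge of the middle 95% of random lists follow. Hedgehog and BMP genes were at 94.3 without background correction, 96.6 with the processed signals and the authors' table, 94.0 with no filter, 94.3 without the member of largest ratio and 86.0 to 92.9 with 1 array. Intestinal genes were at 1.18 with offset 10, 1.46 with the processed signals and the authors' table and 99.3 with both populations above background. Wnt genes were at 91.3 with no filter and 81.0 to 94.3 with 1 array. Gastric stem cell genes were at 92.8 with no filter and 77.9 without shared members. Parietal genes were at 97.3 without shared members or without the member of largest ratio, and 95.5 to 97.8 with 1 array. Tuft genes were at 0.03 with no filter and 1.97 to 24.7 with 1 array. Squamous genes were at 42.8 with no filter. Fibroblast genes were at 98.4 with median centring and 37.0 to 99.8 with 1 array. Reference genes were at 2.66 without the member of largest ratio and 2.09 to 4.96 with 1 array.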

Other observations

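The groups in this paragraph and the next are 11 gene families picked by symbol after the data were seen, so their percentiles among random lists only describe these RNA samples. All 13 measured MHC class I genes had a ratio above 0, with a median of 0.83 at the 99.98th percentile, and H2-K1 (1.14 ± 0.05) was 2-fold higher in GFPhigh on both arrays. Their median was 0.06 under median centring and 0.05 under spike-in centring, and many of these genes are near-identical, so their probes may share transcripts. For comparison, the median of all genes was -0.06, and -0.49 and -0.84 under these centrings. The 34 proteasome subunit genes had a median of -0.23 at the 2.28th percentile, of -0.96 under median centring and -1.01 under spike-in centring. Only 6 of the 34 had a ratio above 0, the largest being Psmb8 (1.08 ± 0.24) and Psmb9 (0.61 ± 0.14), and 0 were 2-fold apart on both arrays. Of 4 complement genes, C4b and Cfi (1.86 ± 0.12) were higher in GFPhigh, with a median of 1.36 at the 99.98th percentile that was 0.59 under median centring and 0.58 under spike-in centring. Of 10 digestive enzyme genes best known from the pancreas, Cela1, Clps (2.09 ± 0.94) and Pnliprp2 (1.34 ± 0.17) were higher in GFPhigh and the amylase gene Amy1 (-1.70 ± 0.12) in GFPlow. Their median was 0.69, and 0.39 under median centring and -0.10 under spike-in centring. Of 6 collagen genes Col11a2 was higher in GFPhigh, with a median of 0.70 that was 0.27 under median centring and -0.08 under spike-in centring.

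Towards GFPlow, 7 of 19 glutathione S-transferase genes were 2-fold higher on both arrays and 0 in GFPhigh, among them Gstm3 (-2.28 ± 0.39) and Mgst3 (-2.24 ± 0.13). The 7 include the close copies Gsta1 and Gsta2, whose probes may share transcripts. The family median of -0.20, at the 13.0th percentile, was -1.17 under median centring and -0.98 under spike-in centring. Of 15 cytochrome P450 genes 3 were higher in GFPlow, Cyp2c65 (-2.68 ± 0.44), Cyp2c66 (-2.54 ± 0.19) and Cyp2d26 (-2.24 ± 0.12), with a median of -0.16 at the 16.1th percentile, and of -0.51 and -0.95 under the same centrings. Of 9 S100 genes 3 were higher in GFPlow, S100a6, S100a14 (-1.76 ± 0.14) and S100a10 (-1.42 ± 0.27), with a median of -0.00 at the 59.4th percentile, and of -0.61 and -0.79. Aldehyde dehydrogenase and aldo-keto reductase genes, 17 measured, had 1 higher in GFPhigh, 2 higher in GFPlow and a median of 0.02 at the 64.2th percentile, and of -0.65 and -0.77. The 75 ribosomal protein genes had a median of -0.36 at the 0.01th percentile, with Rpl14 (-1.13 ± 0.15) 2-fold higher in GFPlow on both arrays. Their median was -0.23 with the processed signals, -1.35 under median centring and -1.14 under spike-in centring. The 74 oxidative phosphorylation genes had a median of -0.04 at the 51.4th percentile, and of -0.86 and -0.83 under median and spike-in centring.

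Of the tests in the rest of this part, the one on the centre of the ratios was chosen before its result was seen, and the others after. More genes were counted as higher in GFPlow (211) than in GFPhigh (138), a share of 39.5% in GFPhigh with a 95% exact binomial interval of 34.4 to 44.9, which covers counting error only. Weaker detection of GFPhigh as the whole cause stays open. Among the 3915 genes of higher average signal, of which 99.6% were above background in both populations on both arrays, the share was 43.1%, with an interval of 36.9 to 49.6. This interval takes the genes as independent, while the counted mitotic and replication genes all went towards GFPlow. Its upper end lies near 50%, and the 50% mark depends on the centre of the ratios, so weaker detection cannot be excluded. Among counted genes above background in both populations the share was 47.3% (41.2 to 53.6), but that filter removes genes low in GFPhigh because they are low, so it decides nothing. The centre of the ratios stays open. Centring each array's gene ratios on their own median gave 47.1% (41.8 to 52.5), but this moves the share towards 50% by itself. Whether cells with low Lgr5 express more genes was not tested.

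The 57 mitotic and DNA replication genes measured had a combined median of -1.28. A signal-dependent bias of the ratios is argued against, because 95% of random lists of the same size and signal had medians between -0.20 and 0.07. Leukocytes in GFPlow are argued against too, since 2 of 34 leukocyte genes were well above background in GFPlow on both arrays. Abundant leukocyte transcripts such as those of Cd74, Tyrobp, Lyz2 and Ptprc were not among them. Still open, and not tested, are a larger share of dividing cells among cells with low Lgr5 and any other difference between the 2 RNA samples, of which there was 1 per population.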
